A study of Mus musculus with 6 samples.

How the data were processed

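Poly(A) RNA-seq was available for 6 libraries of macrophages grown in culture from mouse bone marrow (bone marrow-derived macrophages) on the C57BL/6 background. All mice carried floxed Hdac2 alleles and had received LLC1 cells, a mouse Lewis lung carcinoma line, by vein, and marrow was taken on day 20. Mice without Cre are called WT here (3 libraries) and mice with LysM-Cre, a Cre recombinase placed in the Lyz2 gene and active in myeloid cells, are called KO (3 libraries). Per the labels' protocols, 3 µg of total RNA went into a stranded mRNA kit and single reads of 72 bases were sequenced. The labels give each library as a separate sample of its group and do not say whether each came from a separate mouse, so p-values measure the spread between these samples, which may be partly technical.

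The deposited file was a single table of 17313 genes with Ensembl identifiers and 1 whole-number value per gene and library. The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.10a, Picard 2.27.4, featureCounts 2.0.3 and DESeq2 1.36.0 with the mm10 build, without giving the role or order of each tool. The deposited values were treated as a score, a normalized unit rounded to whole numbers, and not as raw reads. Their totals per library were nearly equal, from 5704313 to 5837994. In WT 2 the values 6, 17, 29, 40 and 52 never occurred, a pattern left when whole reads are multiplied by a factor above 1 and rounded. The factor estimated from such patterns was 1.095 for WT 2, 0.932 for KO 1, 0.954 for KO 2 and 0.974 for KO 3, which puts the reads counted in these libraries, to the nearest 10000, at 5290000, 6240000, 6090000 and 5850000. The factors of WT 1 and WT 3 could not be read from the values, so their depth is unknown. Rounding lost the exact reads, so no count model was fitted and no counting interval is given. The lowest sum of a gene over the 6 libraries was 3, no gene lay on the mitochondrial chromosome, and no pair of libraries held identical values.

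Of the genes, 17297 were found by identifier in GENCODE release M21, and 99.1% of these had the same start and end there, so coordinates are given as in the deposited table (mm10). Exonic lengths were taken from that annotation as the union of a gene's exons.

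The test planned for counts was replaced by the one fixed for normalized values. Genes with a value of at least 10 in at least 3 libraries (13260) were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment at 0.05. All 6 libraries entered with the group as the only term. Differences are KO minus WT on the log2(value + 1) scale, which understates the change of genes with low values. Hdac2 and Lyz2 were also tested with an exact permutation test, whose smallest two-sided p with 3 against 3 is 0.1. For gene lists, camera was run with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way. Of 46 lists, 42 had at least 3 tested genes. The others were mitochondrially encoded genes (0 tested), eosinophil (2), erythroid (2) and epithelial or lung carcinoma markers (1). Lengths were computed with Python 3.11.15 and pandas 2.3.3.

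The groups, the tests, the gene lists, the alternatives and the rule for naming genes were set before the data were examined. The rule takes Hdac2, Lyz2, Hdac1, Hdac3, Hdac8 and Sp1. Among genes past the threshold with a mean value of at least 20 and no overlap between groups, leaving out predicted models and pseudogenes, it takes up to 12 higher and 12 lower by size of change. It also takes up to 4 members with the smallest p of each described list and, where fewer than 10 genes pass, the 10 with the smallest p, given as values. Sex-linked genes are given only as a list. Of the genes the rule takes, 2 are not reported here.

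The pipeline was tested on simulated data with the real means and residual spreads, in which 200 of the 13260 genes were changed. With all 6 libraries it recovered 64% of genes changed 2-fold and 81% of those changed 4-fold, with 5 false calls. With the layout that leaves out WT 1 it recovered 61% and 84%, with 11 false calls. The simulated noise was independent between genes, while the first principal component of the real libraries held 78.6% of the variance. These shares and false calls therefore need not hold for the real data.

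The alternatives were other scalings, filters, pseudocounts and thresholds, leaving out each library in turn, the replicate number as a block and other windows around the targeted genes. DESeq2 and limma-voom had been listed for counts and were not run.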

Results

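Gene expression was measured in macrophages grown from the marrow of LLC1-bearing mice whose floxed Hdac2 gene was intact (WT, 3 libraries) or targeted by LysM-Cre (KO, 3 libraries). Hdac2 encodes a class I histone deacetylase, an enzyme that removes acetyl groups from histones. The comparison asks how loss of HDAC2 in the myeloid lineage changes the RNA of macrophages from tumour-bearing mice. Values are read counts per gene scaled by a factor per library and rounded, referred to as scaled counts, with library totals from 5704313 to 5837994.

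Hdac2 (ENSMUSG00000019777, chromosome 10, 36974544 to 37001889, mm10) was read first, because it checks the group names. It stood at 534, 482 and 518 scaled counts in the WT libraries and at 392, 387 and 375 in the KO libraries, 511 ± 26.6 against 385 ± 8.74 (SD, n = 3 each). Every KO library lay below every WT library, and the KO mean was 0.752 of the WT mean. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), the lysozyme gene that carries the Cre, was at 1089 ± 48.1 in WT and 942 ± 11.5 in KO (SD, n = 3), again without overlap. The deleted exon is not given in the sources used here, so reads from exons that remain would count for Hdac2.

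The log2 difference was -0.41 ± 0.057 (SE) for Hdac2 and -0.21 ± 0.048 for Lyz2, the latter -0.14 under cyclic loess. The exact permutation test gave 0.1 for each gene, the smallest p this design allows. Neither passed the limma test after Benjamini-Hochberg adjustment over all genes, both with an adjusted p of 0.158. Without WT 1 both passed, with adjusted p-values of 0.0142 for Hdac2 and 0.0498 for Lyz2. Over all alternatives the adjusted p ranged from 0.0036 to 0.979 for Hdac2 and from 0.0054 to 0.979 for Lyz2. None of the 17297 genes with an exonic length had a mean value above 1 per exonic base, and Lyz2 was among those closest to it, at 0.772 over 1316 bases against 0.10 over 4474 bases for Hdac2.

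The other class I deacetylases and the transcription factor Sp1 overlapped between the groups. Hdac1 stood at 355 ± 18.6 in WT and 358 ± 5.86 in KO, Hdac3 at 476 ± 12 and 485 ± 8.08, and Hdac8 at 151 ± 16.4 and 153 ± 11.5 (SD, n = 3). Sp1 was at 1392 ± 51.0 and 1316 ± 31.9, a log2 difference of -0.08 that turned to 0.0085 under cyclic loess. The limma adjusted p-values were 0.918, 0.767, 0.931 and 0.343.

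**Figure D1:**
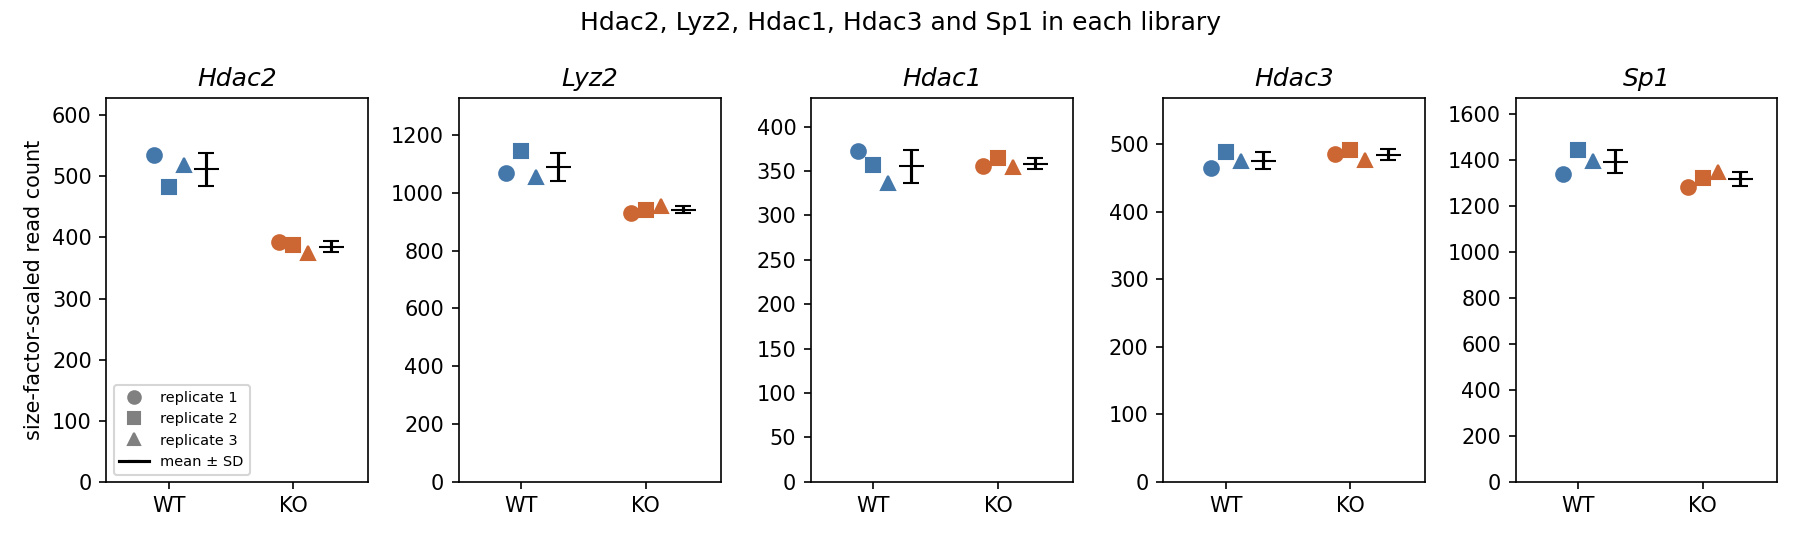
Scaled read counts (vertical axis, from 0) of Hdac2, Lyz2, Hdac1, Hdac3 and Sp1 in the 3 WT and 3 KO libraries, with the replicate number as the symbol and the mean ± SD in black. Hdac2 ran from 482 to 534 in WT and from 375 to 392 in KO.

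The libraries did not fall apart by genotype alone. The first principal component of the tested genes held 78.6% of the variance and placed WT 2 at -72.0 and WT 3 at -54.6, against 12.7 for WT 1, 19.9 for KO 3, 42.5 for KO 2 and 51.5 for KO 1. Across genes, WT 1 correlated with the KO libraries at Pearson r of 0.978, 0.983 and 0.981, and with WT 2 and WT 3 at 0.944 and 0.961. Genes are not independent replicates, so these values only describe the libraries.

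The sex-linked list split the libraries in the same way. Xist, the RNA that silences an X chromosome in female cells, stood at 5243 in WT 1, 0 in WT 2 and 74 in WT 3, and at 4726, 4997 and 3298 in KO 1, KO 2 and KO 3. The Y-linked genes were high in WT 2 and WT 3. Ddx3y was at 308 and 745 there, at 44 in WT 1, at 10 in KO 1 and at 0 in KO 2 and KO 3. Kdm5d was at 473 and 482 there and at 34 in WT 1, Eif2s3y at 412 and 441 and at 36, and Uty at 179 and 432 and at 23, and none of the 3 exceeded 5 in a KO library. WT 1 and WT 3 therefore held reads of both kinds. KO 1 did so at a low level, with Kdm5d at 5 and Eif2s3y at 4 besides Ddx3y at 10, and Uty at 0. All 3 KO libraries had the high Xist pattern and only 1 WT library shared it, so genotype and this split overlap. Each gene list described below is therefore also given as the difference between the KO mean and WT 1. Without WT 1 genotype and the split coincide, so results of that fit cannot tell them apart. The sex-linked list was called lower in KO (5 genes tested, camera adjusted p = 0.0037, and adjusted p = 0.648 with an estimated correlation), with 4 genes lower and none higher when adjusted over the list alone, and the call ended with a mean value of at least 100 as the filter (adjusted p = 0.0724).

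**Figure D2:**
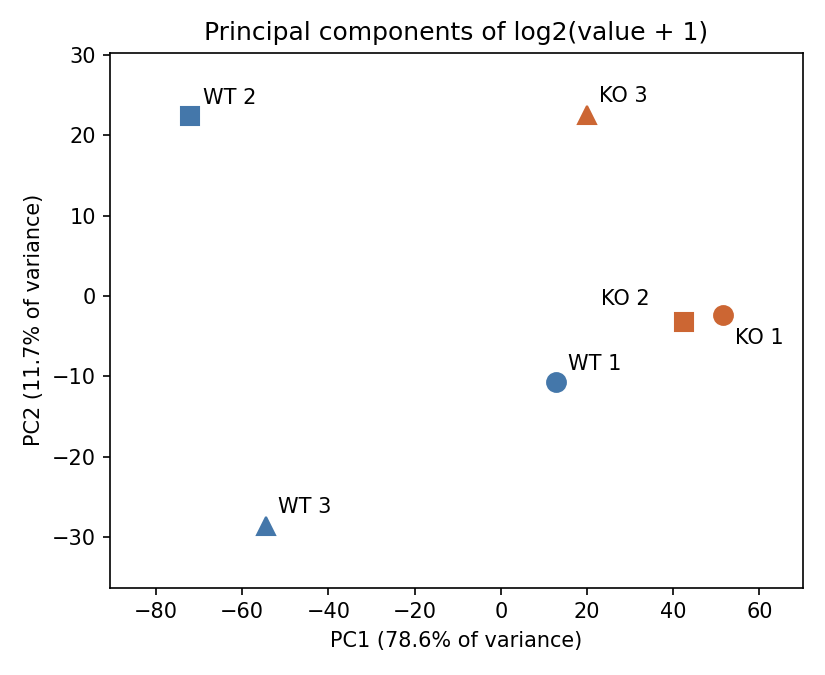
First and second principal components of log2(value + 1) over the 13260 tested genes, 1 point per library, with 78.6% and 11.7% of the variance on the axes. WT 1 lay at 12.7 on the first component, beside KO 3 at 19.9, and WT 2 and WT 3 lay at -72.0 and -54.6.

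The genes with the smallest p in the test of KO against WT, given as values, were led by Mical3, which encodes a monooxygenase acting on actin, at 324 ± 5.86 scaled counts in WT and 460 ± 7 in KO (SD, n = 3). Tulp3, a regulator of trafficking to cilia, was at 249 ± 11.7 and 356 ± 8.89, Krba1 at 77.0 ± 11.5 and 152 ± 11.5, and 2700081O15Rik at 160 ± 14.6 and 276 ± 27.2. Shroom4, an actin-binding protein gene on the X chromosome, was at 19.3 ± 7.09 and 77.3 ± 9.07, and Ebf2, a transcription factor of mesenchymal cells, at 10 ± 2.65 and 37.7 ± 2.08. Zfp354a, a zinc finger gene with close relatives that can share reads, was at 3, 4 and 3 in WT and 24, 22 and 19 in KO. Lower values in KO were seen for Tnfsf13os, at 84.3 ± 14.0 and 27.0 ± 5.57, and 4921516A02Rik, at 25 ± 1.73 and 6.33 ± 1.53, and Hdac2 was the remaining gene. Tnfsf13os and 4921516A02Rik are annotated as antisense transcripts, and as the counting by strand is not stated, their reads cannot be told from those of genes they overlap.

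With limma on all 6 libraries, 0 of 13260 genes were higher and 0 lower in KO at an adjusted p under 0.05 (smallest adjusted p = 0.158). At an unadjusted p under 0.05 there were 1947 higher and 1283 lower, 3230 or 24.4% of the genes. The balance depended on the setting, with 1072 higher and 1128 lower where a mean value of at least 100 was the filter. Under upper-quartile rescaling it was 2035 and 973. In 2141 genes every KO library lay above every WT library and in 1774 below, together 29.5% of the genes. Chance gives 10% as an average over all splits of the libraries. Genes that move together can carry a single split far from that average, so this excess alone does not show an effect of genotype. Without WT 1, 1691 genes were higher and 672 lower past the adjusted threshold, and all 10 genes above were among them. The WT libraries in that fit, WT 2 and WT 3, are those with low Xist, so it cannot separate genotype from the sex-linked split. For the 2363 genes past the threshold in that fit, WT 1 lay nearer the KO mean than the mean of WT 2 and WT 3 in 1996 (84.5%). Leaving out any other library gave 0. The count at an unadjusted p was 1422 without KO 1, 1588 without KO 2, 1715 without WT 3 and 2051 without WT 2. Array weights, chosen after the data were seen, gave 2803 higher and 2242 lower genes with weights of 0.366, 0.265 and 3.675 for WT 1, WT 2 and WT 3, so this fit compares KO mainly with WT 3. With WT 1 as the only WT library, assumed to vary as the KO libraries do, 0 genes passed and 826 had an unadjusted p under 0.05.

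Among the lists called higher in KO, that of fibroblast and marrow stroma genes had the largest median difference. All 14 tested members were higher in the KO mean, with a median log2 difference of 1.00. Fbn1, which encodes the matrix protein fibrillin, was at 2334, 698 and 690 in WT and 3257, 2955 and 2751 in KO. Pdgfrb, a growth factor receptor of mesenchymal cells, was at 818, 196 and 204 and at 1269, 1082 and 931. Cxcl12, the chemokine that retains blood progenitors in marrow, was at 400, 194 and 132 and at 1699, 1094 and 413, and Thy1 at 14, 8 and 10 and at 19, 19 and 26. The list was called higher (camera adjusted p = 4.0e-05) but not with an estimated correlation (adjusted p = 0.648), and 11 genes were higher when adjusted over the list alone against 0 over all genes. WT 1 lay above WT 2 and WT 3 in 13 of the 14 genes, and the median difference between the KO mean and WT 1 was 0.23. Without WT 1, 11 members passed over all genes.

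**Figure D3:**
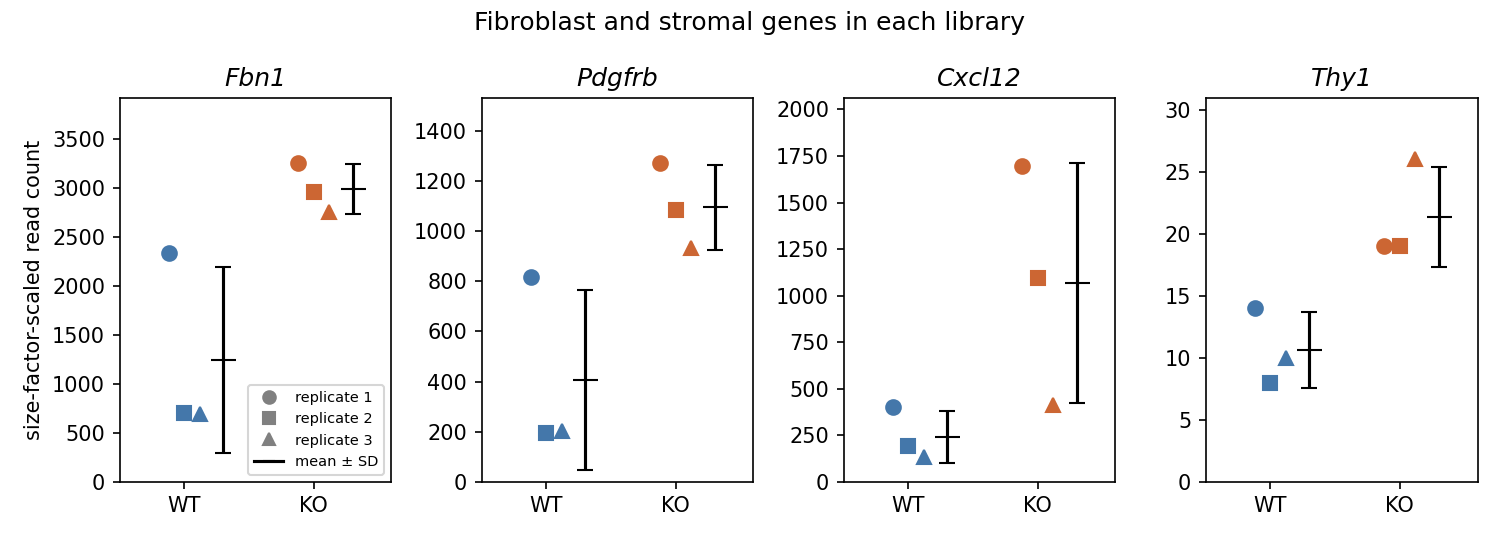
Scaled read counts (vertical axis, from 0) of Fbn1, Pdgfrb, Cxcl12 and Thy1 in the 3 WT and 3 KO libraries, with the replicate number as the symbol and the mean ± SD in black. For Fbn1, WT 1 at 2334 stood nearer the KO libraries, 2751 to 3257, than WT 2 and WT 3, at 698 and 690.

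Matrix and remodelling genes included members on both sides. Col14a1, a fibril-associated collagen, was at 117 ± 124 in WT and 491 ± 71.8 in KO, and Mmp14, a membrane-bound metalloproteinase, at 480 ± 332 and 1035 ± 54.6 (SD, n = 3). The macrophage elastase Mmp12 was at 1952 ± 287 and 1211 ± 175, and the collagenase Mmp13 at 541 ± 77.3 and 404 ± 31. Of 26 tested genes 16 were higher, the median was 0.52, and the list was not called with all libraries (camera adjusted p = 0.161, and adjusted p = 0.744 with an estimated correlation). No member passed when adjusted over the list alone or over all genes. Without WT 1 the median was 0.78 and the camera adjusted p 0.00035, but adjusted p = 0.637 with an estimated correlation in that fit, with 15 members higher and 3 lower past the threshold over all genes. The median difference between the KO mean and WT 1 was 0.04.

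Progenitor and mitotic genes were the other 2 lists called higher. Among 8 tested genes of blood progenitors, Hoxa9 was at 26.3 ± 26.6 in WT and 88.3 ± 14.2 in KO, Meis1 at 52 ± 8.72 and 80.3 ± 11, and Gata2 at 14.0 ± 5.29 and 33.0 ± 6.25, all 3 transcription factors, while the surface marker Cd34 was at 212 ± 43.7 and 142 ± 14.6 (SD, n = 3). The list median was 0.80 (camera adjusted p = 0.0475, and adjusted p = 0.648 with an estimated correlation), with 3 genes higher and 1 lower when adjusted over the list alone, 0 over all genes, and 4 higher without WT 1. All 28 tested genes of the G2 and M phases were higher in the KO mean, with a median of 0.27 (camera adjusted p = 0.00039, and adjusted p = 0.713 with an estimated correlation), and no single gene passed when adjusted over the list alone or over all genes. Cenpa was at 486 ± 10.3 and 556 ± 45.1, Aurkb at 364 ± 63.9 and 456 ± 19.9, Plk1 at 414 ± 76.2 and 517 ± 20.9, and Cdc20 at 360 ± 56.5 and 435 ± 26.5. Against WT 1 alone the medians were 0.43 and 0.08. The progenitor median was 0.52 without WT 3 and the mitotic one 0.07 without WT 2. The progenitor call ended in 11 of 16 alternatives. These include setting aside the 2 libraries with low Xist and entering them as a covariate, which are the same comparison with WT 1 alone. The mitotic call ended only there.

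Macrophage genes lay slightly lower in KO. Of 19 tested identity genes 4 were higher in the KO mean, with a median of -0.18. Cd68 was at 1115 ± 57.2 in WT and 985 ± 32.4 in KO, Adgre1, which encodes the F4/80 antigen, at 2327 ± 145 and 2025 ± 74.5, and Cebpa, a myeloid transcription factor, at 978 ± 119 and 779 ± 49.2 (SD, n = 3). The lysosome and phagocytosis list had a median of -0.18 over 31 genes, with the proton pump subunit Atp6v0d2 at 1335 ± 169 and 892 ± 36.6, the scavenger receptor Cd36 at 2182 ± 188 and 1593 ± 89.6, the protease Ctss at 1189 ± 56.6 and 998 ± 18.2, and Atp6v1h at 731 ± 45.7 and 621 ± 8.33. The osteoclast list had a median of -0.25 over 10 genes, with Acp5, the tartrate-resistant phosphatase, at 227 ± 58.1 and 101 ± 8.33, Clcn7 at 1495 ± 130 and 1276 ± 37.4, and Dcstamp, needed for cell fusion, at 143, 615 and 472 in WT and 28, 58 and 147 in KO. The list of tumour-associated macrophage genes had a median of -0.17 over 25 genes, with Mmp12 as above, Cd274, which encodes PD-L1, at 480 ± 104 and 284 ± 35.7, Gpnmb at 3194 ± 349 and 2531 ± 136, and Lgals3 at 1093 ± 110 and 891 ± 46.5.

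These 4 lists were called lower, with camera adjusted p-values of 0.00065 for identity, 1.0e-05 for lysosome, 0.013 for osteoclast and 0.0079 for tumour-associated genes. With an estimated correlation none was called (adjusted p = 0.648 for the first 3 and 0.657 for the last). Adjusted over the list alone, 5 lysosome genes and 4 osteoclast genes were lower, none of the identity or tumour-associated genes, and 0 over all genes. Without WT 1, 3 identity, 10 lysosome, 5 osteoclast and 5 tumour-associated genes were lower past the threshold over all genes, and 1, 2, 0 and 3 higher, and the tumour-associated call ended (adjusted p = 0.118) with a median of -0.20. Under cyclic loess, which removes a shift that depends on abundance, the tumour-associated median was -0.03 and the call ended (adjusted p = 0.08), and the identity and lysosome medians were -0.11 and -0.09. Without WT 2 the lysosome and tumour-associated medians were -0.12 and -0.10. Against WT 1 alone the medians were -0.12, -0.11, -0.12 and -0.11.

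Interferon and antigen presentation genes were also lower in the KO mean. Rsad2, the antiviral protein viperin, was at 603 ± 19.6 in WT and 377 ± 82.5 in KO, Cmpk2 at 489 ± 41.5 and 346 ± 59.1, and Stat2 at 1290 ± 22.0 and 1090 ± 71.1 (SD, n = 3), within a type I interferon list of 33 genes with 3 higher and a median of -0.15. In the MHC class I list 1 of 18 genes was higher and the median was -0.17. Nlrc5, which drives class I transcription, was at 793 ± 29.9 and 648 ± 39.3, and the peptide-loading factor Tapbp at 1355 ± 93.6 and 1153 ± 63.9. H2-D1 was at 1304 ± 99.1 and 1092 ± 55.4 and H2-K1 at 1151 ± 71.0 and 1006 ± 38.9, a pair of near-identical genes whose reads can be shared. The type I interferon list (camera adjusted p = 0.00028) and the MHC class I list (0.00019) were called lower, but not with an estimated correlation (adjusted p = 0.713 and adjusted p = 0.648). Adjusted over the list alone, 0 and 1 genes were lower, and 0 over all genes. In both lists WT 1 lay with WT 2 and WT 3 or above them, with medians of -0.33 and -0.16 for the KO mean against WT 1. The interferon median was -0.25 without WT 2 and -0.27 without KO 1, and without WT 1 the call ended (adjusted p = 0.0765, median -0.12).

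The interferon gamma and MHC class II lists were not called. In the first, with 22 genes and a median of -0.13 (camera adjusted p = 0.0697, and adjusted p = 0.713 with an estimated correlation), Igtp was at 320 ± 12 in WT and 270 ± 8.89 in KO, Irf1 at 614 ± 54.4 and 512 ± 20.9, and the immunoproteasome subunit Psmb8 at 491 ± 8.02 and 439 ± 21.4 (SD, n = 3). In the second, with 11 genes and a median of -0.25 (camera adjusted p = 0.150, and adjusted p = 0.648 with an estimated correlation), the invariant chain gene Cd74 was at 123, 264 and 312 in WT and 89, 69 and 124 in KO, Ifi30 at 547 ± 75 and 436 ± 12.1, and H2-Ob at 28.0 ± 13.9 and 57.3 ± 4.04. Adjusted over the list alone, 0 and 1 genes were lower. Against WT 1 alone the medians were -0.17 and -0.05. Without WT 1, 1 gene was higher and 1 lower in the first list and 2 higher and 6 lower in the second, past the threshold over all genes.

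Lists of M1-like and M2-like markers of macrophage activation were not called, and members of each lay on both sides. Among 19 M2-like genes 8 were higher in the KO mean, with a median of -0.11. The transcription factor Egr2 was at 690 ± 200 in WT and 302 ± 90.4 in KO, the receptor Clec7a at 916 ± 151 and 562 ± 52.7, the interleukin 4 receptor gene Il4ra at 1088 ± 190 and 1479 ± 65.6, and Arg1, which encodes arginase, at 11.3 ± 2.52 and 25.3 ± 7.57 (SD, n = 3). Among 14 M1-like genes 7 were higher, with a median of 0.13. The cytokine signalling inhibitor Socs3 was at 39.3 ± 31 and 156 ± 28.5, the prostaglandin synthase gene Ptgs2 at 99.3 ± 85.0 and 301 ± 28.2, and the costimulatory ligand Cd80 at 236 ± 65.3 and 380 ± 20.4. Neither list was called (camera adjusted p = 0.412 and 0.631, and adjusted p = 0.713 and adjusted p = 0.862 with an estimated correlation). Adjusted over the list alone, 1 M2-like gene was lower, and 3 M1-like genes were higher and 2 lower, against 0 over all genes. Without WT 1, 2 M2-like genes were higher and 5 lower, and 4 M1-like genes higher and 1 lower, past the threshold over all genes, with medians of -0.24 and 0.34. Under cyclic loess the M1-like median was 0.08. Against WT 1 alone the medians were -0.05 and -0.13, so the M1-like median had the opposite sign.

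Most genes of respiration, protein synthesis and the oxidative stress response were lower in the KO mean. None of 27 nuclear genes of oxidative phosphorylation was higher in the KO mean (median -0.10), with Cox4i1 at 480 ± 22.9 in WT and 421 ± 4.73 in KO, Uqcrc2 at 570 ± 7.09 and 518 ± 11.5, Sdhc at 505 ± 34.6 and 440 ± 8.08, and Sdha at 1217 ± 75.4 and 1096 ± 13.7 (SD, n = 3). Of 28 ribosomal protein genes 1 was higher (median -0.10), with Rpl4 at 953 ± 15.1 and 897 ± 6.11, Rpl7 at 382 ± 2.31 and 354 ± 4.51, and Rpl8 at 614 ± 33.5 and 566 ± 17, a family whose reads can be shared with pseudogenes. Of 18 NRF2 target and oxidative stress genes 2 were higher (median -0.18), with Prdx1, a peroxidase, at 755 ± 86.5 and 597 ± 28.0, the ferritin light chain gene Ftl1 at 382 ± 23.1 and 325 ± 17, the glutathione synthesis gene Gclc at 621 ± 48.4 and 531 ± 18.1, while malic enzyme Me1 was higher, at 101 ± 33.7 and 213 ± 44.0. The 3 lists were called lower (camera adjusted p = 7.6e-05, 0.00078 and 0.00087) but not with an estimated correlation (adjusted p = 0.648, adjusted p = 0.713 and adjusted p = 0.648), and no member passed when adjusted over the list alone or over all genes. Without WT 1, 1 respiration gene and 7 stress genes were lower and 1 stress gene higher past the threshold over all genes. Against WT 1 alone the medians were -0.08, -0.07 and -0.07, and without WT 2 the ribosomal median was -0.05. Over all tested genes the median difference went from 0.43 for genes with a mean log2 value under 4 to -0.09 for those above 10, so abundant genes as a whole lay lower in KO. Under cyclic loess, which removes such a shift, the medians of the 3 lists were -0.11, -0.08 and -0.12. The 3 camera calls with the preset correlation held there.

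**Figure D4:**
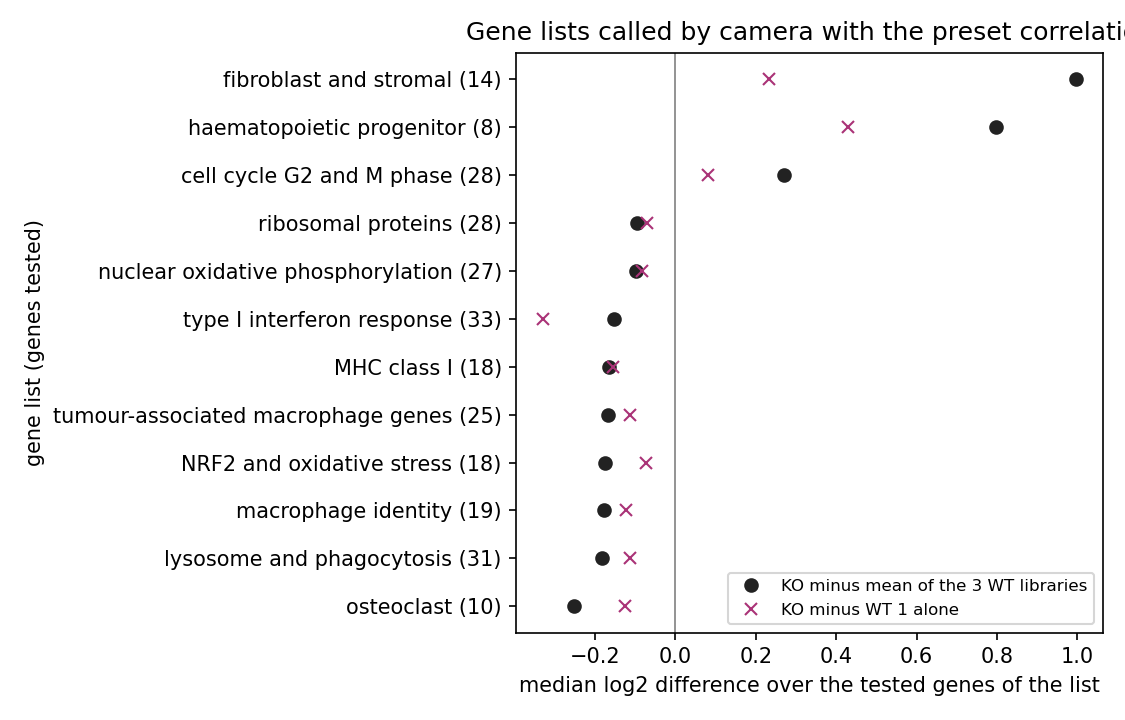
Median log2 difference (horizontal axis) over the tested genes of each list called by camera with the preset correlation, apart from the sex-linked list, for KO against the 3 WT libraries (points) and against WT 1 alone (crosses). The stromal list lay at 1.00 against all WT libraries and at 0.23 against WT 1, and the type I interferon list at -0.15 and -0.33.

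Deacetylase, corepressor and Sp/Klf genes were not called as lists. Besides Hdac2, the deacetylase list of 17 genes held Hdac7 at 254 ± 28.6 in WT and 395 ± 33.5 in KO, Hdac6 at 342 ± 10.1 and 372 ± 2.08, and Hdac9 at 573 ± 61.2 and 492 ± 31.4 (SD, n = 3). Of 28 genes of the complexes that hold HDAC1 and HDAC2, Rcor2, a CoREST family subunit, was at 20.0 ± 11.4 and 63.3 ± 6.66, Sap30 at 278 ± 10.3 and 246 ± 13.1, Mta3 at 525 ± 49.9 and 449 ± 48.7, and Chd4 at 2784 ± 146 and 2610 ± 32.7, the last with a difference that turned positive under cyclic loess. Of 15 Sp and Klf factors, Klf7 was at 473 ± 40.8 and 569 ± 13.4, Klf6 at 1488 ± 106 and 1254 ± 48.8, Klf10 at 626 ± 74.0 and 503 ± 61.9, and Klf13 at 1285 ± 115 and 1120 ± 60.7. The medians were 0.02, -0.02 and -0.02, the corepressor median turning to 0.03 and the Sp/Klf one standing at -0.0015 under cyclic loess, with camera adjusted p-values of 0.774, 0.374 and 0.611, and adjusted p-values of 0.862, 0.825 and 0.825 with an estimated correlation. Adjusted over the list alone, 1 deacetylase gene was higher and 1 lower and no corepressor or Sp/Klf gene passed, against 0 over all genes. Without WT 1, 1 deacetylase gene was higher and 1 lower past the threshold over all genes, 1 corepressor gene was higher, and 1 Sp/Klf gene was higher and 3 lower, with medians of 0.05, -0.05 and -0.11. The medians of the KO mean against WT 1 were 0.05, 0.0053 and 0.02, so the corepressor and Sp/Klf medians had the opposite sign.

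The lists of cell cycle inhibitors, lipid handling genes and chemokines were not called. Their members with the smallest p did not overlap between the groups, which a choice by p favours, and 29.5% of all tested genes did not overlap either. Among 22 p53 targets and cell cycle inhibitors, Phlda3 was at 344 ± 26.9 in WT and 444 ± 10.7 in KO, Cdkn2a at 114 ± 17.1 and 168 ± 16.8, Cdkn2b at 119 ± 30.1 and 213 ± 33.6, and Sesn2 at 512 ± 45.6 and 618 ± 12.3 (SD, n = 3), with Cdkn2a and Cdkn2b encoding inhibitors of the cyclin D kinases. The list median was 0.14 and 15 genes were higher (camera adjusted p = 0.0697, and adjusted p = 0.648 with an estimated correlation), with 5 higher and 1 lower when adjusted over the list alone. Among 22 lipid handling genes with 9 higher and a median of -0.11 (camera adjusted p = 0.150, and adjusted p = 0.713 with an estimated correlation), the fatty acid binding proteins Fabp4 and Fabp5 were at 258 ± 42.7 and 172 ± 12.7 and at 428 ± 57.5 and 320 ± 24.2, and Dgat2, which makes triglycerides, at 15.7 ± 4.62 and 36 ± 9, with Cd36 as above. Here 3 genes were higher and 8 lower when adjusted over the list alone. Among 17 chemokines, Ccl6 was at 646 ± 118 and 414 ± 74.6, Ccl9 at 1060 ± 146 and 809 ± 68.8, and Cx3cl1 at 296, 161 and 143 in WT and 340, 322 and 375 in KO, with Cxcl12 as above, and no gene passed when adjusted over the list alone (median 0.06, which turned to -0.08 under cyclic loess, camera adjusted p = 0.846, and adjusted p = 0.900 with an estimated correlation). None of the 3 lists had a gene past the threshold over all genes, and without WT 1 they had 6 higher and 1 lower, 4 and 10, and 5 and 2, the chemokine median then being 0.18. Under cyclic loess the lipid median was -0.05. Against WT 1 alone the medians were 0.04, -0.03 and -0.21.

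In all, camera with the preset correlation called 13 of 42 lists, 3 higher and 10 lower. With an estimated correlation 0 lists were called, and with fry 0 (smallest adjusted p = 0.0698).

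Genes near the targeted loci were compared with the rest, since a Cre line carries flanking DNA of its founder. Within 10 Mb of Lyz2, 19 of 77 tested genes (24.7%) had an unadjusted p under 0.05, against 24.3% elsewhere, and within 10 Mb of Hdac2, 15 of 72 (20.8%) against 24.4%. Fisher's exact test, two-sided, gave 0.895 and 0.582 (Benjamini-Hochberg adjusted 0.895 for both), with Hdac2 and Lyz2 left out. With limma on all 6 libraries 0 of these genes passed the adjusted threshold. Without WT 1, 29 of the 77 and 72 genes together passed, where 2363 of all 13260 tested genes did.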

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

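Cyclic loess, the sex markers as a covariate, array weights, the test without WT 2 and WT 3, the unadjusted threshold and, for the gene lists, totals without the 50 most abundant genes were chosen after the result was seen. The count of 0 genes past the adjusted threshold held under the other scalings, filters, pseudocounts and stricter thresholds and under cyclic loess. It ranged from 0 to 2363 when each library was left out (0 to 1691 higher, 0 to 672 lower), above 0 only without WT 1. The sex covariate marked WT 2 and WT 3, so its KO difference was that from WT 1 alone, the same as without WT 2 and WT 3. With 1 WT library behind it, that comparison cannot show whether the count holds. Array weights gave 5045 genes (2803 higher, 2242 lower), with a weight of 3.675 for WT 3, and an unadjusted threshold 3230 (1947 higher, 1283 lower). The cause of the higher counts without WT 1 and with array weights was not tested, and without WT 1 genotype and the sex-linked split coincide. The count at an unadjusted p under 0.05 ran from 1422 to 4349 with 1 library left out, and was 6356 with array weights, 647 with the sex covariate and 826 without WT 2 and WT 3, where fewer libraries or degrees of freedom remained. The Hdac2 difference kept its sign in all 18 alternatives, from -0.45 to -0.38 with 1 library left out and -0.41 with array weights, and the Lyz2 difference in all 18, from -0.23 to -0.17 and -0.18, and -0.14 under cyclic loess. Both passed without WT 1 and with array weights, and the cause was not tested. With the estimated correlation 0 lists were called and with fry 0, against 13. Among genes near Lyz2 and Hdac2, 0 to 29 passed with 1 library left out, and 34 at an unadjusted p.

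Of the 117 other genes the rule for naming takes, 77 passed without WT 1 and 109 with array weights, and 5 changed sign somewhere. Hdac1 ran from -0.026 to 0.049 with 1 library left out (-4.4e-05 without KO 2), and was -0.058 with the sex covariate and -0.058 without WT 2 and WT 3. Hdac8 ran from -0.037 to 0.11 (-0.0063 without WT 3, -0.032 without KO 2), and was -0.014 under cyclic loess, -0.15 with the sex covariate and -0.15 without WT 2 and WT 3. Il1rl1 ran from -0.037 to 0.10 and was -0.0096 under cyclic loess, where Sp1 stood at 0.0085 and Chd4 at 0.038. The cause of these changes was not tested. Whether the shared replicate numbers pair the samples is not stated. Deviations of same-numbered libraries correlated at 0.53, -0.36 and 0.02. WT 1 correlated best with KO 1, but WT 2 and WT 3 correlated best with KO 3 and KO 2. So few libraries cannot exclude a pairing. With the replicate number as a block 0 genes passed and 13 lists were called. DESeq2 and limma-voom, listed for counts, were not run because the values are not counts. The depth of WT 1 and WT 3 is unknown.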

Other observations

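The tests of genotype, sex, start positions, other saturated genes, an abundance-dependent shift and other splits were chosen after the result was seen, and 2 further gene lists were written after the stromal pattern was seen but before their own values were.

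Markers of other cells lay on both sides. Plac8, a monocyte gene, stood at 40, 2 and 4 scaled counts in WT and 80, 89 and 61 in KO, and Vcan, a proteoglycan of monocytes and of matrix, at 567, 34 and 133 and at 1148, 1104 and 353, within a monocyte list of 13 genes. The basophil protease Mcpt8 was at 36, 0 and 4 and at 94, 75 and 37, while Il1rl1 of the same 3-gene list was at 147, 177 and 156 and at 164, 164 and 158. Of the dendritic cell list, the integrin gene Itgax was at 2024 ± 342 and 1288 ± 209 and the actin bundler Fscn1 at 338 ± 224 and 809 ± 50.03 (SD, n = 3). Of the B cell list, Cd22 was at 182 ± 17.6 and 125 ± 10.8, Igkc at 70.3 ± 37.9 and 17.7 ± 9.07, and Cd79b at 12.7 ± 4.04 and 34 ± 5. These 4 lists had median log2 differences of 0.26, 1.22, -0.07 and -0.25, against WT 1 alone 0.05, 0.68, -0.05 and -0.27, and were not called (camera adjusted p = 0.284, 0.141, 0.850 and 0.631), and no gene passed over all genes with all 6 libraries. Without WT 1 they had 4, 2, 2 and 2 genes higher and 0, 0, 2 and 0 lower past that threshold, and the dendritic median was -0.0056. Under cyclic loess the monocyte and dendritic medians were 0.14 and -0.04.

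Immediate early genes and neuronal genes kept silent by REST, a repressor that works with histone deacetylases, were not called either (camera adjusted p = 0.284 and 0.684). Egr2 was at 690 ± 200 in WT and 302 ± 90.4 in KO, Atf3 at 1067 ± 200 and 696 ± 101, Dusp1 at 539 ± 80.9 and 383 ± 56.9, and Ier3 at 103 ± 52.5 and 196 ± 10.1 (SD, n = 3). Bdnf was at 20, 2 and 2 and at 92, 55 and 32, Kcnh2 at 10.3 ± 3.21 and 23.7 ± 4.04, Tubb3 at 125 ± 97.4 and 340 ± 45.2, and L1cam at 528 ± 89.1 and 379 ± 66.7. The medians were -0.20 and 0.04, the latter turning to -0.05 under cyclic loess, and -0.06 and 0.02 against WT 1 alone. Adjusted over the list alone, 3 of the 8 REST genes were higher and no immediate early gene passed. Without WT 1, 1 immediate early gene was higher and 3 lower past the threshold over all genes, and 3 REST genes were higher and 1 lower, with a REST median of 0.11.

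Genes of the stromal list were higher in the KO mean and, in 13 of 14, in WT 1 than in WT 2 and WT 3, while matrix genes lay on both sides, and WT 2 and WT 3 held stromal genes as well: of a second list of 40 mesenchymal genes that shares none with the first, 33 had at least 100 scaled counts in every library, and the most abundant, Col12a1, stood at 2614, 929 and 1288 in WT and 4061, 3283 and 2487 in KO. A candidate explanation is a larger share of stromal cells among the macrophages of the KO libraries and WT 1: 100% of the second list were higher in KO (median 1.08, above all of 10000 level-matched random lists), and no sort or gate that would remove such cells is stated in the sources used here. Genotype or sex acting on mesenchymal genes would raise the second list too, so it does not tell these causes apart. The random lists drew genes singly, so they do not allow for genes that move together. A list of 39 haematopoietic genes gave mixed support: its median for KO against WT was -0.17 (36 lower, 3 higher), below all of 10000 level-matched lists, whose middle was -0.07, but WT 1 differed from the mean of WT 2 and WT 3 by a median of -0.05, where the mesenchymal list differed by 1.31, and KO from WT 1 by -0.14, so the lower haematopoietic values did not follow the stromal genes in WT 1. Hdac2 genotype as the whole cause would place WT 1 with WT 2 and WT 3, but its median position was 0.860 on a scale from 0 at their mean to 1 at the KO mean, and this is a single library, which excludes nothing. Sex cannot be told apart from genotype here, because WT 1 is the only WT library with the high Xist pattern, and on the stromal list it differed from the KO mean by a median of 0.23.

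The 22 genes with at least 0.6 scaled counts per exonic base, Lyz2 included, differed little between the groups. Values could be held down if the reads were reduced to 1 per start position, which Picard can do, although its role is not given: 0 of 17297 genes had a mean value above 1 per exonic base, and the highest was C1qb at 0.850. Lyz2, at -0.21, lay inside the range of the 21 others, -0.33 to 0.03, with 4 of them lower. Differences of such genes may therefore be understated or shifted. Reads held down in this way would not grow with depth, so the scaling itself could lower such genes in KO. The estimated factors were 0.932, 0.954 and 0.974 for KO 1, KO 2 and KO 3, against 1.095 for WT 2. Those of WT 1 and WT 3 are unknown, and this was not tested. The 21 include Cd68 and Adgre1 of the macrophage identity list, which holds Lyz2 too, and Ctss of the lysosome list, and these lists lay lower in KO. The Lyz2 value thus does not separate an effect of the Cre allele from a shift shared with abundant genes or with those lists, and each stays open.

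No gene passed the adjusted threshold, yet 3230 had an unadjusted p under 0.05. A shift that depends on abundance as the whole cause is argued against by cyclic loess, which removes such a shift and left 2991 genes at that level. The 6 libraries can be split into 3 and 3 in only 10 ways, too few for a share under 0.05: all 10 gave 0 genes past the adjusted threshold, and 1 of the 10, the real split, reached 3230 genes at the unadjusted one, with 2595 as the highest of the others, for WT 1, KO 1 and KO 2 against the rest.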
